A study of Homo sapiens with 12 samples.

How the data were processed

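The 12 libraries were made from total RNA of stable DU145 clones, 3 libraries from each of 4 clones. Per the labels, 500 ng of RNA per sample went into a QuantSeq FWD 3′ mRNA library kit with unique molecular identifiers (UMIs), read on a NextSeq 500. Per the labels, the authors made base calls with bcl2fastq 2.20.0.422, handled UMIs with UMI-tools 1.1.1, trimmed with Trimmomatic 0.36 and aligned to hg38 with STAR 2.7.3a. Reads were counted per gene with featureCounts, version 1.6.3 per the labels and 1.6.4 per the file headers, over exons on 1 strand of a GRCh38-p10 annotation. The deposited values are raw counts per gene, whole numbers without normalization. The deposited DESeq2 table (version 1.20.0 per the labels) gives, per the file headers, a log2 fold change, its standard error on the log2 scale, and a p-value with its adjusted p, for empty vector over TLR3 clones. The 24 per-sample columns of the series tables repeat these samples and were not used here. Untransfected DU145 cells were not analysed here, so a loss in the TLR3 clones cannot be told from a gain in the control clones.

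The files list 58302 genes, of which 28308 had a count in some library. Totals ranged from 4008527 to 5556420 counts, with a median of 5110743.5. CPM values were computed in edgeR over library totals scaled by TMM. Positions came from the count files, and symbols of all 28308 genes with a count from the deposited DESeq2 table. A level of 0 was read as up to 3 counts, per library over its total, or summed over a group where stated. Intervals of count ratios were exact Poisson intervals at 95%, and folds against 0 were computed against the limit of 3 counts. Counts of libraries of the same clone varied more than Poisson sampling alone, with a chi-square per degree of freedom of 3.50 to 11.4.

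These choices were fixed before the data were examined: the comparisons, their tests, the alternatives other than those named below, the gene lists and the rule for naming genes. Raw counts were analysed in R 4.3.3 with edgeR 4.0.16, by TMM normalization, a filter by expression in at least 1 clone (filterByExpr, minimum count 10) and the quasi-likelihood F test. This left 13786 genes. P-values were adjusted by Benjamini-Hochberg, 2-sided, at 0.05, and the SE of a log2 fold change is its size over the square root of F. The 6 TLR3 libraries were compared with the 6 empty vector libraries. Counts summed per clone were compared 2 against 2. A model with 1 mean per clone gave each pair of clones, each TLR3 clone against the mean of the controls, and the 3 ways to split 4 clones 2 against 2. A gene was shared when it passed in the same direction in all 4 pairs of a TLR3 with a control clone. Pairs that share a control are not independent, so 20 simulations of clones with no difference were run for the shared count.

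Named genes were TLR3, the 10 largest rises and 10 largest falls among shared genes that also passed 6 against 6 with a mean of at least 5 CPM and a proper symbol, up to 4 members of each list with the smallest p, and the 5 largest rises and falls of D7 against A6 and C12 against B9. Genes named otherwise were chosen after their values were seen: OAS3, the genes of the replicate numbers, and those in the closing section. The 18 lists held 508 genes. They were TLR3 signalling, interferon response, antigen presentation, NF-kB targets and cytokines, epithelial, mesenchymal, invasion proteases and inhibitors, extracellular matrix and integrins, apoptosis, proliferation, prostate lineage, stemness, TGF-beta signalling, hypoxia and glycolysis, unfolded protein and integrated stress response, cholesterol synthesis, leukocyte markers, and fibroblast and endothelial markers. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, with an estimated correlation, and with fry. Log2 fold changes, medians and principal components came from the same values and fits.

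Alternatives were DESeq2 size factors, no filter on low counts, a filter of 1 CPM in 6 libraries, the replicate number as a block, leaving out each library or each clone, DESeq2 1.42.0, 1 mean per clone, limma-voom with clone as a random effect, thresholds on fold change (1 on the log2 scale, or glmTreat at 1.5-fold), and robust estimation. Leaving out the number 2 libraries of A6 and D7 together was added after seeing the data, and so were the list tests of single clones and of C12 against B9 and D7 against A6, and the block for B9 against the control clones. Whether the numbers in the labels pair libraries was checked from correlations of the deviations from clone means. All 3 same-number pairs of D7 with A6 were over 0.1 (0.106 to 0.463), and so were all 3 of C12 with B9 (0.234 to 0.341), of B9 with A6 (0.136 to 0.246) and of B9 with D7 (0.168 to 0.227). For those comparisons, blocked values are given where they end a call or move a printed count by over 1.5 times, and calls of named genes that the block added are given there or in the closing section. Of the pairs of C12 with A6 and with D7 not every one was over 0.1, so for comparisons that set these against each other blocked values are given in the closing section only. The dispersion of 3 libraries against 3 came from all 12 libraries.

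The methods were tested on simulated data with the spread of libraries within these clones. With 6 against 6, also simulated without differences between clones of a genotype, edgeR called 62.7% of genes changed 1.5-fold. It called 86.6% of those changed 2-fold and 98.5% of those changed 4-fold. With 3 against 3 these shares were 23.9%, 56.7% and 97.0%, and with clone totals, simulated without differences between clones of a genotype, 52.2%, 83.6% and 97.0%. The real B9 and C12 libraries did differ, so the shares for 6 against 6 and for clone totals can be too high for these data. Camera found the 1 list that was shifted, and no other, among genes drawn independently. In the data the estimated correlation was 0.642 for proliferation, so this result may not carry over.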

Results

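Messenger RNA was measured in 12 libraries from DU145 cells, a human prostate carcinoma line grown from a brain metastasis. The cells had been electroporated with a plasmid and selected with G418, and 4 stable clones were compared. Clones A6 and D7 carried the empty vector, and clones B9 and C12 overexpressed TLR3, the endosomal receptor for double-stranded RNA. Each clone gave 3 libraries, numbered 1 to 3 in the labels. Total counts per library ranged from 4008527 to 5556420. Mitochondrial genes took 12.5% to 16.0% of the counts, and 12334 to 13388 genes had at least 10 counts in a library. A count of 0 in a single library allowed a level of up to 0.540 to 0.748 CPM, the usual unit of counts scaled to library size. Intervals and such limits cover counting error only.

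TLR3 was higher in both TLR3 clones than in the controls, and far higher in C12 than in B9. The gene (ENSG00000164342, chromosome 4, 186069152 to 186088069, hg38) had a mean of 66.3 ± 14.3 CPM (SD, n = 3) in C12 and 3.35 ± 2.11 CPM (SD, n = 3) in B9. It had 0.437 ± 0.219 CPM in A6 and 0.225 ± 0.0375 CPM in D7 (SD, n = 3 each). The counts summed to 1042 in C12, 48 in B9, 7 in A6 and 3 in D7. By pooled counts, B9 was 9.51-fold above the controls, with an exact Poisson 95% interval of 4.75 to 21.1. C12 was 197-fold above them, with an interval of 107 to 412, and 20.7-fold above B9, with an interval of 15.5 to 28.3. With 6 libraries against 6, the log2 fold change was 6.59 (SE 1.13, edgeR adjusted p = 0.00324). The difference between the TLR3 clones was itself called, at a log2 fold change of 4.36 (SE 0.27, edgeR adjusted p = 1.9e-08). With clone A6 or clone D7 left out, the 6 TLR3 libraries against the remaining 3 gave 7.14 (adjusted p = 0.0714) and 6.23 (adjusted p = 0.134). With clone as a random effect in limma-voom it was 5.12 and did not pass (adjusted p = 0.276). The kit reads the 3′ end of transcripts, and reads in any vector part of the transgene transcript were not examined here. These counts and folds may therefore hold transgene RNA only in part.

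**Figure D1:**
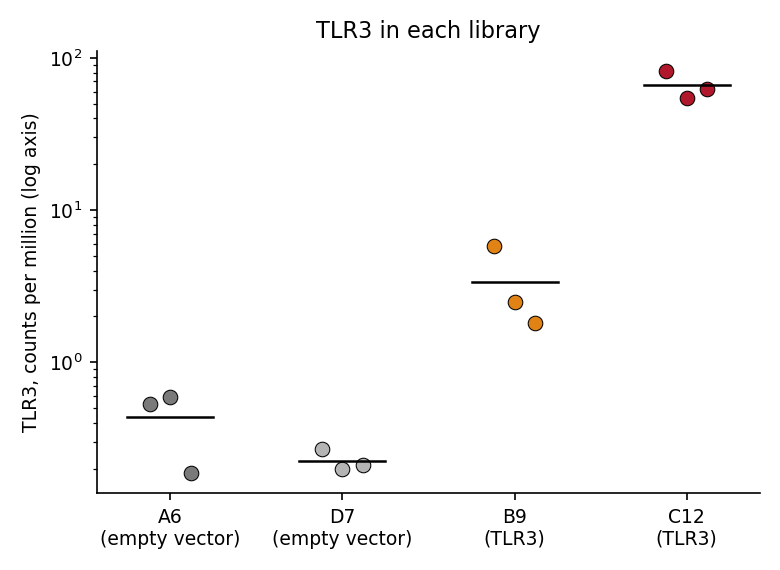
TLR3 in CPM (log axis) for each of the 12 libraries, grouped by clone. The 3 C12 libraries lie between 54.1 and 82.1, the 3 B9 libraries between 1.82 and 5.76, and every control library below 0.6.

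On the first principal components of all tested genes, B9 and C12 each lay apart from the controls, but not along a single axis of genotype. The first component held 26.9% of the variance and set B9 apart, with scores of 28.18 to 37.11. The second held 21.7% and set C12 apart, with scores of -28.86 to -33.65. The scores of A6 and D7 overlapped on both. The third held 10.2%, and there A6 library 2 (28.36) and D7 library 2 (21.0) stood away from the other 10 libraries.

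**Figure D2:**
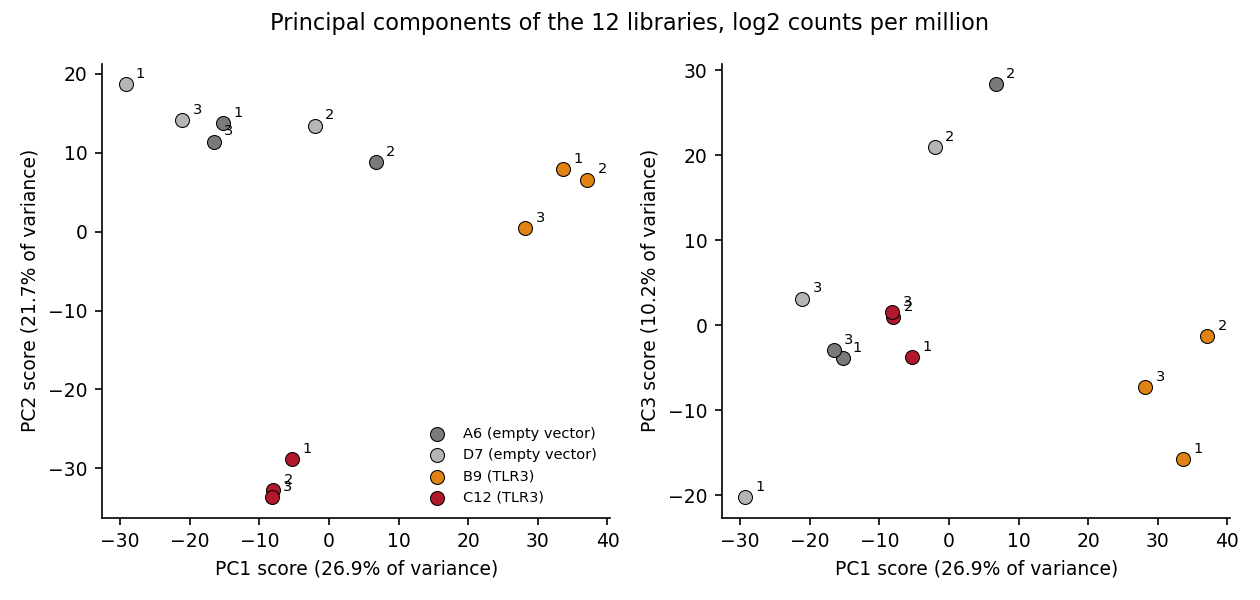
Scores of the 12 libraries on principal components 1 to 3 of log2 CPM, with points coloured by clone and the share of variance on each axis. B9 and C12 lie apart from the controls on different components, and the number 2 libraries of A6 and D7 lie highest on component 3.

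Genes that differed between TLR3 and empty vector clones, whichever clones were set against each other, were compared next; the series names invasion and apoptosis as its subjects. CD70, a ligand of the tumour necrosis factor family, rose from 47.7 ± 8.69 to 106 ± 7.04 CPM (SD, n = 6 each; log2 fold change 1.15, SE 0.11, edgeR adjusted p = 1.0e-05). RAC2 rose from 4.94 ± 1.09 to 15.8 ± 2.27 CPM (1.66, SE 0.16, edgeR adjusted p = 1.2e-05). ELOVL2, an elongase of very long chain fatty acids, rose from 8.79 ± 1.50 to 28.0 ± 7.67 CPM (1.66, SE 0.18, edgeR adjusted p = 3.5e-05). C15orf48, which encodes a small mitochondrial protein, fell from 230 ± 48.8 to 62.4 ± 13.3 CPM (-1.88, SE 0.15, edgeR adjusted p = 3.9e-06). ANXA1, the phospholipid-binding annexin A1, fell from 170 ± 22.0 to 62.2 ± 29.1 CPM (-1.45, SE 0.23, edgeR adjusted p = 0.0017).

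Other genes among the 10 largest rises were the actin-capping protein CAPG (1.26), the protocadherin PCDHB16 (1.15), the collagen receptor MRC2 (from 6.39 to 13.8 CPM), ZNF428 (1.04), COL28A1 (1.03) and ARMCX2 (1.01), as log2 fold changes. TLR3 led that list. Among the 10 largest falls were RHOV (-2.03), the cytokine IL11 (-1.76), the neurofilament gene NEFL (-1.70), IGFBP4 (-1.50) and FAM83A (-1.47). BCHE (butyrylcholinesterase), ROBO1 (a receptor for SLIT guidance proteins) and MT1A (a metallothionein) had no count in any C12 library. Against the limit of 3 counts over that clone, C12 was at least 80.4-fold lower than the controls for BCHE, at least 48.5-fold for ROBO1 and at least 76.9-fold for MT1A. Whether each gene stayed called in every pair of clones with a library left out was not tested. Leaving out any single library ended the call of all TLR3 against all empty vector libraries for 0 of these 20 genes. With clone D7 left out, ANXA1 (adjusted p = 0.0567), CAPG (0.118), MT1A (0.168) and ROBO1 (0.112) lost theirs.

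Of 13786 genes tested, 657 passed an adjusted p of 0.05 in edgeR with 6 libraries against 6, 351 higher and 306 lower with TLR3. Of these, 87 passed in the same direction in all 4 pairs of a TLR3 clone with a control clone, 34 higher and 53 lower. The 4 pairs by themselves gave 999 calls for B9 against A6, 1702 for B9 against D7, 574 for C12 against A6 and 667 for C12 against D7. With the replicate number as a block, B9 against A6 gave 1745 and B9 against D7 gave 2627. In 20 simulations in which no clone differed from another, the 4 pairs shared 0 genes. Such data leave few genes to share, so this does not cover clones that differ for reasons other than TLR3. The labels do not say that the libraries of a clone were separate cultures, so p-values here measure the spread between these samples, and at the level of clones the comparison is 2 against 2. How the clones are related to each other is not given. The 657 became 379 without A6 library 1, 402 without A6 library 3, 334 without D7 library 1 and 326 without D7 library 3. It became 1020 without A6 library 2, and 1416 without the number 2 libraries of both controls. With clone D7 left out it was 88, with A6 left out 238 and with C12 left out 2004, and with clone as a random effect in limma-voom it was 238. The 87 became 53 without A6 library 1, 55 without B9 library 2, 152 without the number 2 libraries of both controls and 133 without a filter on low counts.

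**Figure D3:**
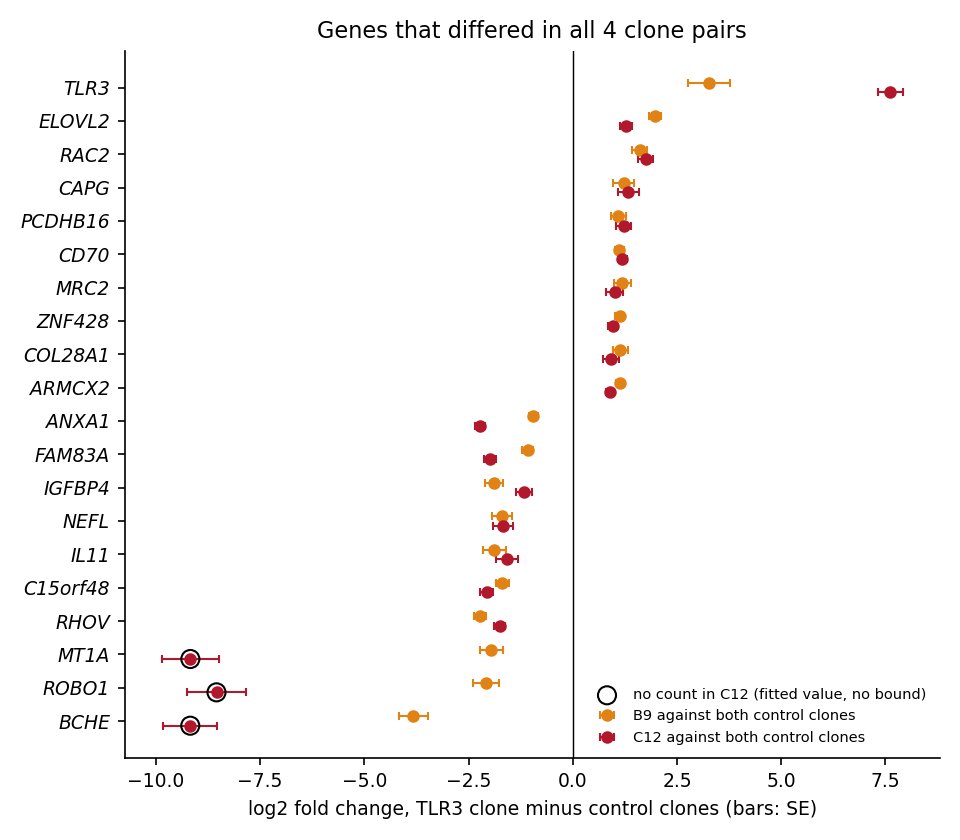
Log2 fold change of each TLR3 clone over the mean of the control clones, for TLR3 and the other genes with the largest changes shared by all 4 clone pairs (bars: SE of the edgeR fit). Each named gene lies on the same side of 0 in B9 and C12, and circles mark genes without a count in C12.

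With counts summed per clone, 2 totals against 2, no gene passed in edgeR. CD70 had a log2 fold change of 1.13 (SE 0.13) there, RAC2 1.66 (SE 0.19) and C15orf48 -1.90 (SE 0.20). The number of genes with an unadjusted p under 0.05 was 1287. DESeq2 on the same totals called 80 genes, and edgeR without a filter on low counts called 31.

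Gene lists fixed beforehand gave small shifts between genotypes. By camera, a test of a list against all other genes, 4 of 18 lists passed at the preset correlation, and 0 with an estimated correlation or with fry. Each of these asks for a shift in 1 direction. Proliferation genes were lower: 5 of 36 measured members fell and 31 did not pass, with 10 lower when adjusted over the list alone. The replication licensing factor CDC6 fell by 0.76 on the log2 scale, the transcription factor MYBL2 by 0.64, cyclin D1 (CCND1) by 0.61 and the helicase subunit MCM7 by 0.39. The list's median was -0.30 (camera adjusted p = 1.13e-06; adjusted p = 0.967 with an estimated correlation). Its mean per library, relative to the 12-library mean, was 0.268 to 0.340 in the number 1 and 3 control libraries, but -0.201 in A6 library 2 and -0.0511 in D7 library 2. It was -0.124 to -0.498 in B9 and -0.0416 to 0.144 in C12. With clone B9 left out, camera gave an adjusted p of 0.395 for this list. Leaving out clones ended the calls of CCND1 (D7, adjusted p = 0.14) and of CDC6, MYBL2 and MCM7 (A6, D7 or B9, 0.058 to 0.379). Left-out libraries ended 3 of these calls: CDC6 without A6 library 1 (adjusted p = 0.0511), D7 library 1 (0.0602) or D7 library 3 (0.0521), MYBL2 in 7 of 12 such fits (0.0504 to 0.0746) and MCM7 in 10 of 12 (0.0521 to 0.105). MYBL2 kept its call without A6 library 2, D7 library 2, B9 library 3 or C12 library 2 or 3, and MCM7 without A6 library 2 or C12 library 3.

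The interferon response list was slightly higher over the TLR3 libraries, a shift that lay mainly in B9. Against the mean of the controls, its median was 0.33 in B9 and 0.05 in C12. Camera gave an adjusted p of 0.000927 and 0.746, or 0.150 and 0.957 with an estimated correlation. With 6 libraries against 6, 2 of 29 measured members rose and 27 did not pass, with 5 higher when adjusted over the list alone. STAT2, a subunit of the transcription factor ISGF3, rose by 0.54 (SE 0.10, edgeR adjusted p = 0.00387), and IFI6 by 0.63 (SE 0.17, edgeR adjusted p = 0.0406). DDX58, which encodes the RNA sensor RIG-I, stood at 0.60 (adjusted p = 0.0734) and MX1 at 0.70 (0.0735). The list's median was 0.18 (camera adjusted p = 0.0167; adjusted p = 0.641 with an estimated correlation). IFI6 lost its call in 9 of 12 fits without 1 library (adjusted p = 0.0575 to 0.112), all but those without A6 library 2, B9 library 2 or C12 library 1. With a clone left out, STAT2 lost its call for D7 (0.0505) and IFI6 for A6, D7 or B9 (0.0873 to 0.353). The list's call ended without B9 library 3 (0.0994), and with clone D7 (0.0784) or B9 (0.479) left out.

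The antigen presentation and cholesterol synthesis lists were also slightly higher over the TLR3 libraries, each mainly in a different clone. Against the mean of the controls, the antigen presentation median was 0.325 in B9 and 0.008 in C12. The cholesterol median was -0.01 in B9 and 0.37 in C12. What follows is for 6 libraries against 6, unless stated. In the antigen presentation list 3 of 15 measured members rose and 12 did not pass, also 3 when adjusted over the list alone. They were B2M (0.29), the light chain of MHC class I, the proteasome activator PSME1 (0.33) and the peptide-trimming ERAP2 (0.52). The median was 0.14 (camera adjusted p = 0.0265; adjusted p = 0.641 with an estimated correlation). In the cholesterol list 1 of 22 rose, NSDHL (0.43), and 4 when adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.0374; adjusted p = 0.967 with an estimated correlation). Without 1 library the antigen presentation call ended for A6 library 3 (0.0716) and B9 library 3 (0.0994). The cholesterol call ended for A6 library 2 (0.183), A6 library 3 (0.058), D7 library 2 (0.0999) and C12 libraries 1 (0.155), 2 (0.252) and 3 (0.194). With clone B9 left out the antigen presentation median was -0.00392 (0.648), and with C12 left out the cholesterol median was -0.0219 (0.584). The first call also ended without clone A6 (0.189), and the second without A6 (0.193) or D7 (0.0628). B2M lost its call without A6 library 3 (0.0749), D7 library 1 (0.0544), D7 library 3 (0.0874), B9 library 1 (0.0623) or B9 library 3 (0.0698). PSME1 lost it in 10 of 12 such fits (0.0606 to 0.0938; not without A6 library 2 or C12 library 1), ERAP2 in 9 (0.0508 to 0.102; not without A6 library 2 or C12 library 2 or 3) and NSDHL in 9 (0.0673 to 0.098; not without A6 library 2 or B9 library 1 or 2). With a clone left out, B2M, PSME1 and ERAP2 lost it for A6, D7 or B9 (0.055 to 0.435) and NSDHL for A6, D7 or C12 (0.176 to 0.38).

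None of the 4 lists closest to invasion passed camera, which asks for a shift in 1 direction. By the mixed test of fry, which allows both directions, all 4 passed. Its adjusted p was 6.3e-08 for epithelial, 7.0e-11 for mesenchymal, 0.0406 for invasion proteases and inhibitors and 6.3e-08 for matrix and integrins. The mixed test sets no list against other genes. It passed every list but unfolded protein and integrated stress response (0.204), cholesterol synthesis (0.0523) and the marker lists of other cell types. Hypoxia and glycolysis (0.0267) and apoptosis (0.0260) were among those that passed. Of 28 measured epithelial genes the keratins KRT8 (-0.66) and KRT18 (-0.76) fell and KRT19 (0.44) rose, with 2 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.189). Of 18 mesenchymal genes moesin (MSN, 0.39), fibronectin (FN1, 0.61) and fibrillin 1 (FBN1, 1.09) rose, with 5 higher and 2 lower when adjusted over the list alone (0.805). Of 22 invasion proteases and inhibitors only the urokinase receptor PLAUR passed, at -0.80, and likewise 1 when adjusted over the list alone (0.805). Of 28 matrix and integrin genes 4 rose and 5 fell, or 5 and 6 when adjusted over the list alone (0.955). Examples were COL6A1 (0.90) and SDC1 (-0.38). FN1 lost its call in 9 of 12 fits without 1 library (adjusted p = 0.0541 to 0.124; not without A6 library 2 or C12 library 1 or 3). PLAUR lost it in 8 (0.0529 to 0.0747; not without A6 library 3, D7 library 3 or C12 library 1 or 2). FBN1 lost it without A6 library 1 (0.0572), D7 library 1 (0.0561) or B9 library 3 (0.0574). With clone D7 left out, KRT18 (0.179), KRT19 (0.261), MSN (0.198), SDC1 (0.176) and FBN1 (0.294) lost their calls. So did SDC1 (0.0734) and FBN1 (0.0911) without A6, MSN (0.0721) without B9, and FN1 and PLAUR without A6, D7 or B9 (0.0763 to 0.434).

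In the TLR3 signalling list TLR3 and the kinase RIPK1 (0.34) were the 2 of 19 measured genes that rose, and adjusted over the list alone the count was also 2 (camera adjusted p = 0.955). Of 34 apoptosis genes 1 rose, the initiator caspase CASP10 (0.65), and 1 when adjusted over the list alone (0.955). Of 23 NF-kB targets and cytokines only IL11 passed, lower, also when adjusted over the list alone (0.589). Of 25 TGF-beta genes TGFB2 (-0.65) and BMP4 (-1.12) fell, also 2 when adjusted over the list alone (0.955). Of 19 stemness genes ALDH7A1 (0.41) rose and BMI1 (-0.53) fell, with 2 higher and 2 lower when adjusted over the list alone (0.955); the median was -0.03, while the mean and the camera direction were positive. Of 9 prostate lineage genes NCAM1 (0.63) rose and the basal keratin KRT15 (-1.36) fell, with 2 higher and 1 lower when adjusted over the list alone (0.902). None passed among 28 hypoxia and glycolysis genes (0.816) or 28 genes of the unfolded protein and integrated stress responses (0.589), also when adjusted over the list alone. Of the markers of other cell types, 2 leukocyte genes (FCER1G and CD68) and 1 fibroblast or endothelial gene (COL1A1) were measurable, and none passed (0.955 and 0.589). Without 1 library, RIPK1 lost its call in 10 of 12 fits (0.0638 to 0.122; not without A6 library 2 or C12 library 2) and KRT15 in 10 (0.0507 to 0.122; not without B9 library 3 or C12 library 2). ALDH7A1 lost it in 7 (0.064 to 0.0844; not without A6 library 2 or 3, B9 library 1 or 2 or C12 library 1) and CASP10 in 6. Those 6 were the fits without A6 library 1 (0.0629), D7 library 1 (0.0656), D7 library 3 (0.0788), B9 library 2 (0.0524), B9 library 3 (0.058) or C12 library 2 (0.0567). With a clone left out, TGFB2 lost its call for A6 (0.128) and D7 (0.072), BMP4 for A6 (0.167) and D7 (0.0607) and KRT15 for B9 (0.1). RIPK1 lost it for any of the 4 clones (0.0596 to 0.29), CASP10 and NCAM1 for A6, D7 or B9 (0.068 to 0.327), and ALDH7A1 and BMI1 for A6, D7 or C12 (0.0595 to 0.363).

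Each TLR3 clone was also set against the mean of the controls. The direct test between these clones is given with C12 against B9. Over all 13786 tested genes, 2244 passed in B9, 1088 higher and 1156 lower. In C12, 981 passed, 520 higher and 461 lower. With the replicate number as a block, B9 gave 3077. Counts of list members in each clone are to be read beside these totals. In B9, 17 of 36 proliferation genes fell, 28 when adjusted over the list alone, among them CDC6 (-1.10), MYBL2 (-0.94) and MCM7 (-0.56). With the replicate number as a block, 26 of the 36 fell. Of 29 interferon genes in B9, 9 rose and OAS3 fell (-0.45), or 12 and 1 when adjusted over the list alone (12 and 2 with the block), and 6 of 15 antigen presentation genes rose, 7 when adjusted over the list alone. In C12, 10 of 22 cholesterol genes rose, 15 when adjusted over the list alone, among them DHCR7 (0.67), NSDHL (0.65), MSMO1 (0.60) and FDFT1 (0.38). Camera gave an adjusted p of 4.67e-10 for proliferation, 0.000927 for interferon and 0.0021 for antigen presentation in B9, and 1.67e-07 for cholesterol in C12. None of these held with an estimated correlation: the values were adjusted p = 0.475, 0.150, 0.230 and 0.117 with an estimated correlation. By fry, which does not set a list against other genes, they passed, at an adjusted p of 0.0314, 0.00105, 0.00105 and 0.00132. In B9 fry also passed the epithelial (0.0466) and mesenchymal (0.00627) lists and COL1A1 (0.0247), which camera did not. In C12, 1 interferon gene rose (STAT2, 0.46), 1 proliferation gene fell (CCND1, -0.70) and 2 antigen presentation genes rose (PSMB8 and PSME1). The counts were 1, 1 and 3 when adjusted over the list alone, and in B9 no cholesterol gene rose and 2 fell, 1 when adjusted over the list alone (2 with the replicate number as a block). The 4 lists closest to invasion did not pass camera in either clone. Of 22 invasion proteases and inhibitors 5 rose and 3 fell in B9, or 6 and 3 when adjusted over the list alone, and none passed in C12, also when adjusted over the list alone. Set directly against B9, C12 had 1 of them higher and 2 lower, or 2 and 4 when adjusted over the list alone or with the block. Matrix and integrin genes had 4 higher and 8 lower of 28 in B9 and 7 and 1 in C12, or 5 and 10 and 10 and 6 when adjusted over the list alone. Epithelial genes had 4 and 4 of 28 in B9 (4 and 7 with the block) and 3 and 3 in C12, or 4 and 6 and 3 and 4 when adjusted over the list alone. Mesenchymal genes had 4 and 1 of 18 in B9 and 3 and 2 in C12, or 5 and 1 and 4 and 3 when adjusted over the list alone. Apoptosis genes had 5 higher and 1 lower of 34 in B9, also when adjusted over the list alone. With the block these were 5 and 4, or 6 and 5. In C12, 3 apoptosis genes rose and 0 fell, also when adjusted over the list alone. Set directly against B9, C12 had 3 of them higher and 3 lower, or 4 and 3 when adjusted over the list alone (5 and 3, or 5 and 4, with the block).

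**Figure D4:**
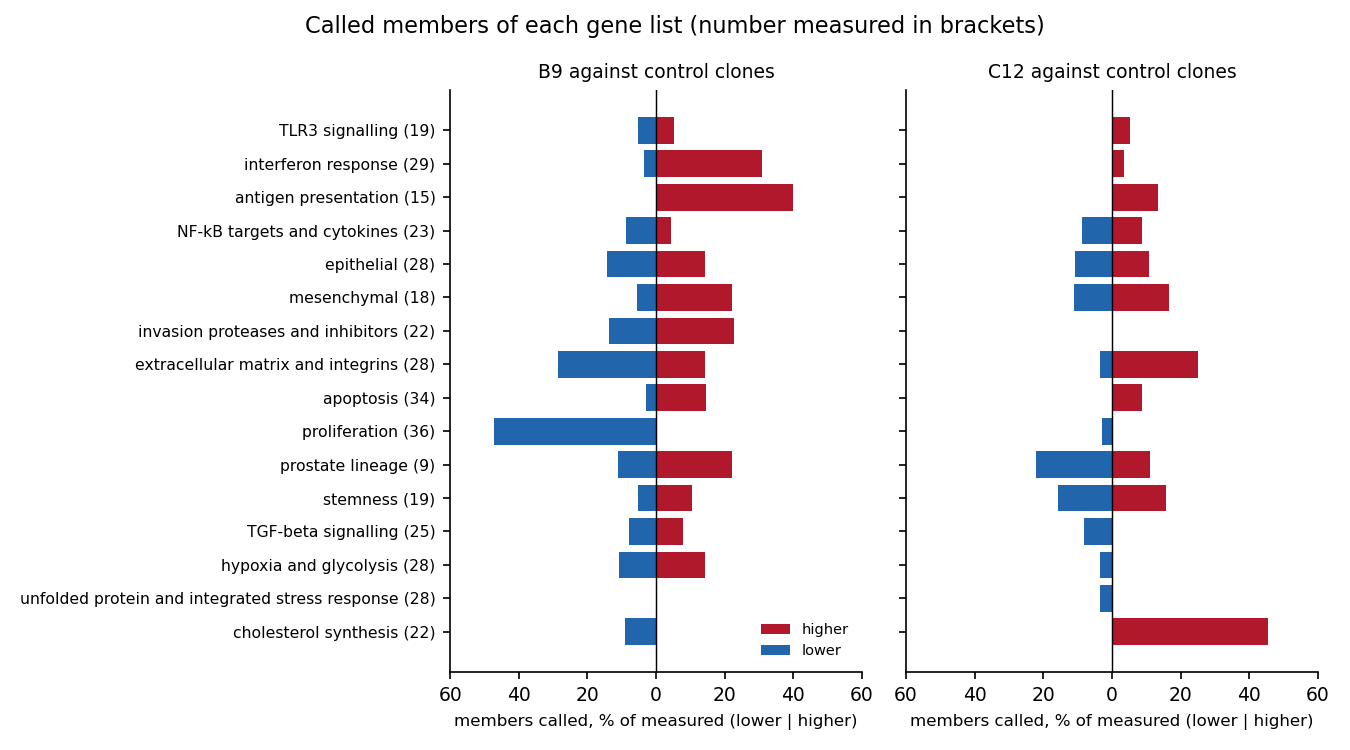
Called members of each gene list as a percentage of its measured members, higher to the right and lower to the left, in the comparisons named above each panel. Proliferation genes reach 17 lower of 36 in B9, and cholesterol genes 10 higher of 22 in C12. Over all 13786 tested genes, 2244 were called in B9 and 981 in C12.

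The TLR3 clones differed directly from each other in 1769 genes, 907 higher and 862 lower in C12. The caveolar coat gene CAVIN2 stood at 128 ± 1.91 CPM in C12 and 2.21 ± 0.517 in B9 (SD, n = 3 each; log2 fold change 5.82, SE 0.18, edgeR adjusted p = 2.2e-12). FSTL5 (5.22) and GKN1 (6.08) were also higher in C12, and so was the pseudogene ZNF826P (4.52). ZNF550 had 145 counts in C12 and 1 in B9, a ratio of 138 with an exact Poisson 95% interval of 24.4 to 5500. The schlafen gene SLFN5 (-3.21) was lower in C12, as were BCHE, ROBO1 and MT1A, at least 5.19-fold, 11.4-fold and 19.4-fold below B9. MTND1P23 (-4.86), a nuclear copy of a mitochondrial gene that can share its reads, varied within clones, at 127 ± 192 CPM in D7 and 273 ± 201 in B9 (SD, n = 3 each).

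Between C12 and B9, 6 lists passed camera at the preset correlation and 0 with an estimated correlation. Cholesterol genes were higher in C12 (12 of 22, 15 when adjusted over the list alone, median 0.47, adjusted p = 1.92e-06; adjusted p = 0.174 with an estimated correlation). Proliferation genes were higher too (6 of 36, 17 when adjusted over the list alone, median 0.35, adjusted p = 2.16e-06; adjusted p = 0.518 with an estimated correlation). Matrix and integrin genes went both ways, 7 higher and 2 lower of 28 over all genes and when adjusted over the list alone (median 0.21, adjusted p = 0.0226; adjusted p = 0.588 with an estimated correlation). Interferon genes had 9 lower and 2 higher of 29, over all genes and when adjusted over the list alone (median -0.23, adjusted p = 0.0172; adjusted p = 0.255 with an estimated correlation). Antigen presentation genes had 3 lower and 1 higher of 15, or 4 and 1 when adjusted over the list alone (median -0.27, adjusted p = 0.0402; adjusted p = 0.342 with an estimated correlation). Stemness genes had 4 lower and 2 higher of 19, again also when adjusted over the list alone (median -0.56, adjusted p = 0.0185; adjusted p = 0.342 with an estimated correlation). With the replicate number as a block the antigen presentation list no longer passed (0.055), 17 proliferation genes were higher, and 2504 genes passed in all. Stemness genes then had 6 lower and 2 higher, or 9 and 3 when adjusted over the list alone, and VIM (-0.35), PLAUR (0.69), CDC6 (0.62) and MYBL2 (0.56) gained calls. By fry, without the block, cholesterol (0.00172), interferon (0.00357), antigen presentation (0.00811) and stemness (0.0116) passed, and proliferation (0.105) and matrix (0.133) did not. It also passed the mesenchymal (0.00341) and prostate lineage (0.0239) lists and COL1A1 (0.0314), which camera did not. The 1769 became 1022 without B9 library 1, 867 without B9 library 2, 969 without C12 library 2 and 914 without C12 library 3.

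Few genes differed between the empty vector clones. TGM2, a transglutaminase, stood at 110 ± 9.57 CPM in D7 and 61.6 ± 5.11 in A6 (SD, n = 3 each; log2 fold change 0.84, SE 0.12, edgeR adjusted p = 0.0168). The long non-coding RNA LRRC75A-AS1 stood at 209 ± 11.5 and 121 ± 17.3 CPM (SD, n = 3 each; 0.79, SE 0.11, edgeR adjusted p = 0.0168). These were the 2 genes called by edgeR, with 458 at an unadjusted p under 0.05 and 14 called by DESeq2. Without a filter on low counts edgeR called 39, 24 higher and 15 lower in D7. No list passed camera and no list member was called over all genes, while 2 TGF-beta genes were lower in D7 when adjusted over the list alone. With the replicate number as a block 6 genes passed, among them BCHE (1.35, adjusted p = 0.0184) and RHOV (0.85, adjusted p = 0.0118), which are also among the largest falls with TLR3 and were higher in D7. The antigen presentation, NF-kB, proliferation and hypoxia lists then each had 1 gene higher in D7 when adjusted over the list alone. The count was 0 without A6 library 1, D7 library 1, D7 library 2 or D7 library 3, 1 without A6 library 3 and 4 without A6 library 2. LRRC75A-AS1 lost its call in the 4 fits with a count of 0 (adjusted p = 0.0594 to 0.227), and TGM2 in these and without A6 library 3 (0.0594 to 0.168).

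Changes in B9 and C12 were related across genes, though modestly. Of genes higher in B9 than in A6, 47 were also higher in C12 than in D7, where independent lists would share 10.9, and 81 were lower in both, against 13.2. With the control clones exchanged, the overlaps were 65 against 16.6 and 77 against 18.7. CD70, RAC2, C15orf48 and ANXA1 were among these genes in both choices. Across the 13786 genes, which are not independent replicates, the log2 fold changes B9 minus A6 and C12 minus D7 had a Pearson correlation of 0.280 and a Spearman correlation of 0.202. The exchanged controls gave 0.237 and 0.118. D7 minus A6 with C12 minus B9, which sets no TLR3 clone against a control, gave 0.0576 and 0.118. By rank, the exchanged choice was thus no higher than this reference. Without a filter on low counts the first r was 0.0639.

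The 4 clones can be split 2 against 2 in 3 ways, and with 1 mean per clone the split by genotype gave the most calls. It gave 1347, with 663 higher and 684 lower. D7 and C12 against A6 and B9 gave 569, and D7 and B9 against A6 and C12 gave 367. Without a filter on low counts the last 2 were 1012 and 683. Leaving out D7 library 3 took the first to 889, and leaving out the number 2 libraries of both controls took it to 2699. The 569 became 318 without D7 library 3, 348 without B9 library 1, 281 without B9 library 2, 311 without C12 library 2 and 371 without C12 library 3. The 367 became 230 without A6 library 1, 237 without B9 library 1, 195 without B9 library 2, 218 without C12 library 2 and 216 without C12 library 3.

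The deposited DESeq2 table holds the ratio of empty vector over TLR3 clones. It gives TLR3 a log2 fold change of -6.71 (SE 1.01, DESeq2 adjusted p = 1.4e-08), which is a higher level with TLR3. Of 15680 genes with an adjusted p there, 882 were under 0.05, 454 higher and 428 lower with TLR3, and 647 of them were among the 657 called by edgeR.

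Libraries with the same number in different clones shared a pattern, which was compared only after the values were seen. HES1, a transcriptional repressor of the Notch pathway, was at 511 to 1050 CPM in the 4 number 1 libraries and at 47.5 to 131 CPM in the other 8 (log2 fold change 3.09, SE 0.08, edgeR adjusted p = 7.0e-14). The chemokine CXCL8 (2.95) and the immediate-early genes NR4A2 (2.26), EGR3 (2.01), ATF3 (1.97), EGR2 (1.93) and CSRNP1 (1.75) were also higher in the number 1 libraries. With 1 mean per clone, edgeR called 152 genes for number 1 against the others, 153 for number 2 and 167 for number 3. The NF-kB list mean was highest in number 1 and lowest in number 3 in 4 of 4 clones (exact permutation within clones, p = 0.00463, the smallest that 216 permutations give, adjusted p = 0.0278 over 18 lists). The stemness list, which holds HES1, gave the same values. COL1A1, the 1 measurable fibroblast or endothelial gene, was highest in number 1 and lowest in number 2 in 4 of 4 clones, with the same p-values. Each genotype held every number equally often.

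**Figure D5:**
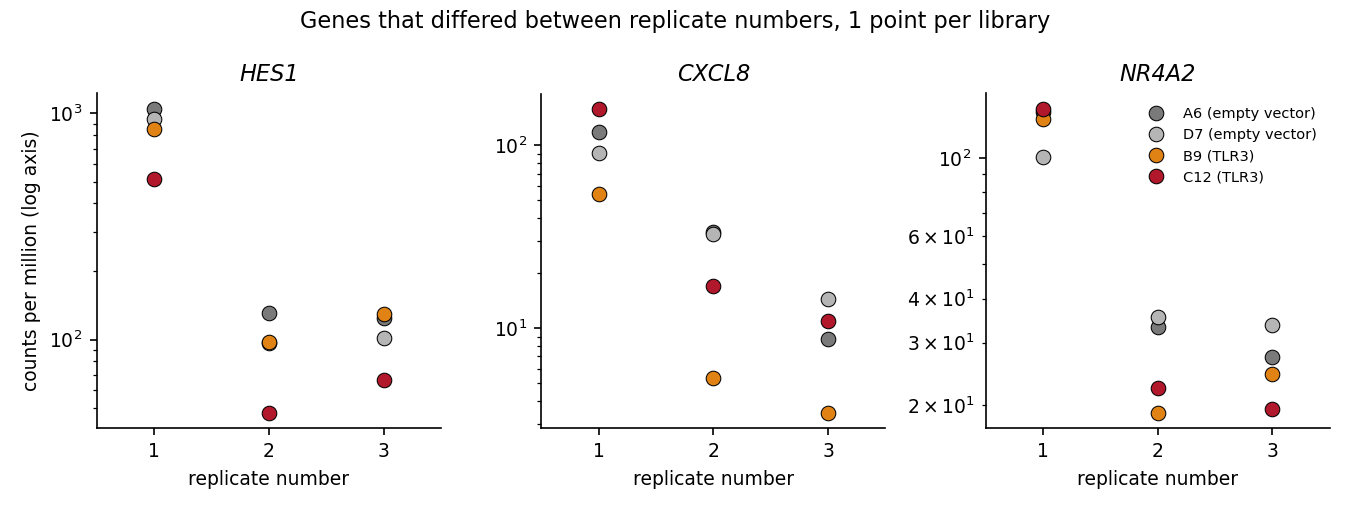
HES1, CXCL8 and NR4A2 in CPM (log axes), 1 point per library, by the replicate number in the labels and coloured by clone. HES1 is at 511 or more in every number 1 library and at 131 or less in the others.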

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

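Tests of deletion, of shared loss, of chromosome 19 zinc finger genes and of TLR3 reads were chosen after the results were seen. The following differed between the TLR3 clones by the direct test of C12 against B9, 1769 genes in all. Genes higher in C12, as log2 fold changes, were TLR3 (4.36), ANGPTL4 (1.37), PSMB8 (0.96), COL1A1 (0.89), ITGA2 (0.78), TNFRSF10D (0.60), DHCR7 (0.58), NSDHL (0.49) and MSMO1 (0.46). Genes lower in C12 were ANXA1 (-1.27), SYP (-1.21), FAM83A (-0.92), ELOVL2 (-0.70), FN1 (-0.59) and NCAM1 (-0.46). MT1A (-7.22), ROBO1 (-6.47) and BCHE (-5.36) had no count in C12, so these fitted values depend on the prior count, and the bounds are at least 19.4-fold, 11.4-fold and 5.19-fold below B9. Lists that passed camera at the preset correlation had medians of 0.47 for cholesterol synthesis, 0.35 for proliferation, 0.21 for matrix and integrins, -0.23 for interferon response, -0.27 for antigen presentation and -0.56 for stemness. None of the 6 passed with an estimated correlation (adjusted p = 0.174 to 0.588 with an estimated correlation), and antigen presentation did not pass with the replicate number as a block (0.055). No group of libraries was tested for single outliers, since each clone has 3.

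TLR3 was lower in B9 than in C12. Reads carried over from C12 would reach the controls alike, but mean CPM in B9 was 10.1 times that in the control clones, which argues against them as the source. Depth of the B9 libraries would change TLR3 by no more than the totals differ, which ranged from 4008527 to 5556420 counts. C12 stood 19.8 times above B9 in mean CPM, which argues against depth too. That ratio restates the observation, and totals do not bound an effect of library composition, so it cannot decide on composition. A lower transgene level in B9 is the biological explanation that may remain, and its integration was not analysed here.

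Many genes differed between C12 and B9 and few between D7 and A6. Whether a spread shared by same-numbered libraries hid differences between the controls cannot be decided. Blocking the number gave 6 calls there, but the block takes this spread as common to all clones. The number 2 libraries of A6 and D7 correlated at 0.463. Those of A6 and D7 correlated at 0.160 and 0.206 with that of B9, and at -0.039 and 0.039 with that of C12. A spread of the controls alone can therefore remain after the block. Segments of changed copy number long enough to shift a running median of 51 tested genes could account for part only. Of the 1769 calls 21.37% lay in such stretches, which hold 11.9% of tested genes. Shorter segments can escape this median and were not tested. A close relation of A6 and D7 cannot be told apart from other reasons. The variance of D7 minus A6 beyond sampling was -7.41% of that of C12 minus B9. It is negative, as the observed variance (0.0543) was under the sampling variance (0.0670), which took the libraries as unpaired. It therefore decides nothing here. The TLR3 level, which differs between B9 and C12, stays open as an untested biological explanation.

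Of 10 genes lost or nearly lost in both TLR3 clones, 7 had at least 4 tested neighbours each within 500 kb, other fallen genes left out. For these 7, a deletion that takes most of those neighbours is unlikely. The 51 neighbours had a median log2 fold change of -0.0333, with 2 at -1 or lower. ZNF347 and ZNF677 lie within 500 kb of each other, and ZNF667 overlaps ZNF667-AS1, so these fallen genes were not counted as each other's neighbours. A deletion that takes only a few genes is not covered by these medians. For BCHE, NAP1L2 and DNAJC15 deletion cannot be told apart from other losses, as 3 neighbours in all were tested (median 0.286, and -0.66 for that of DNAJC15); smaller deletions were not tested. Independent loss of genes at random is unlikely, though not that of genes prone to loss: the 10 fell at least 8-fold against both controls in both clones, of 22 in B9 and 25 in C12, where random lists would share 0.0399, a value that leaves out the shared controls. Chromosome 19 zinc finger genes were 7 of 37 fallen genes and 179 of 13178 others (1-sided Fisher's exact test, p = 7.04e-07), but this p decides nothing, since genes that prompted the test are counted in it and neighbouring paralogs are not independent. A shared origin of B9 and C12 before cloning, a shared gain in A6 and D7, or an effect of TLR3 may each account for this, and they were not tested.

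Other groupings of the 12 libraries were tried, 100 for each result with the real one included. As many as 657 calls came in 2 of 100, and the highest other, 1065, grouped the number 2 libraries of A6 and D7 with the B9 libraries and C12 library 1. These groupings exchange libraries between clones, so where chance is excluded at 0.05 below, this holds for regrouped libraries and not for clones, of which 3 splits exist. It is excluded for the 657 in that sense, while the highest other points to a structure of the samples. The 87 shared genes came in 1 of 100 (highest other 0), the 1347 of the split by genotype in 1 (750), the 569 of D7 and C12 against A6 and B9 in 1 (32) and the 367 of D7 and B9 against A6 and C12 in 1 (195), so chance is excluded for them in the same sense, and that includes 2 splits that do not follow genotype. As many as 4 called lists came in 27 of 100, with 8 as the highest other, so chance is not excluded for the number of lists.

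For 3 libraries against 3 there are 10 groupings, too few for a share under 0.05. The real values and the highest others were 1769 and 0 for C12 against B9, 999 and 11 for B9 against A6, 1702 and 1 for B9 against D7, 574 and 0 for C12 against A6, and 667 and 0 for C12 against D7, each reached in 1 of 10. With the replicate number as a block, B9 against A6 gave 1745 and B9 against D7 gave 2627. Without it, the highest of the 3 other groupings that part every same-number pair was 0 for each. For D7 against A6 the 2 calls were reached in 2 of 10, and the highest other, 45, kept the number 2 libraries of both clones together. Among the 3 other groupings that part every same-number pair, as the real one does, the highest was 1, and the blocked value was 6.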

How the results depend on the processing

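The settings were planned, except leaving out the number 2 libraries of both control clones and the block for B9 against the controls and for lists of single comparisons, which were chosen after seeing the data. Among the called and uncalled named genes and lists, 2312 values kept their side of the threshold, 88 gained a call and 250 lost it. A change of sign without a call in either fit would be counted among the 2312. Another 2, called in the main fit, changed sign. Those 2 were the antigen presentation median with clone B9 left out (-0.00392) and the cholesterol median with clone C12 left out (-0.0219). TLR3 had 7.14 with clone A6 left out, 6.23 with D7 left out and 5.12 in limma-voom with clone as a random effect (adjusted p = 0.276), and passed the threshold in none of these. With C12 left out TLR3 did not pass the filter and had no value. MT1A had an adjusted p of 0.0551 in DESeq2. With clone as a random effect CDC6, MYBL2, MCM7, IFI6, B2M, PSME1, ERAP2, NSDHL, FN1, FBN1, PLAUR, RIPK1, CASP10, BMP4, ALDH7A1 and KRT15 also lost their calls (0.0583 to 0.149). So did B2M (0.095), PSME1 (0.0582), RIPK1 (0.139) and CASP10 (0.0647) without a filter, and RIPK1 (0.0617), NSDHL (0.0508) and FN1 (0.0532) with the filter of 1 CPM. RIPK1 lost it with DESeq2 size factors (0.0502), and PLAUR (0.107), ALDH7A1 (0.0659), NSDHL (0.0765) and the cholesterol list (0.382) without both number 2 control libraries.

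The 657 calls became 238 with clone A6 left out, 88 with D7 left out, 2004 with C12 left out, 1347 with 1 mean per clone, 238 with clone as a random effect, 139 at a log2 fold change of at least 1 and 52 with glmTreat. Without a filter, clone totals gave 31 calls, the shared genes 133, D7 against A6 39, and the other splits of the clones 1012 (D7 and C12) and 683 (D7 and B9), and the correlation was 0.0639. DESeq2 gave 80 calls for totals and 14 for D7 against A6. The shared genes numbered 35 at a log2 fold change of at least 1 in all pairs. With the replicate block, the shared genes were 151, D7 against A6 6, and the 3 splits of the clones 2081, 1103 and 689, while RIPK1 (adjusted p = 0.0564) and KRT15 (0.0581) did not pass 6 against 6. Where the numbers pair the libraries, the block ended no call of a named gene or list but that of antigen presentation between C12 and B9. It added calls of named genes, 2 for D7 against A6, 4 for C12 against B9, 6 for B9 against A6 and 10 for B9 against D7. Those for B9 against A6 were B2M, BIRC3, RECK, KRT15, P4HA2 and CALR. Those for B9 against D7 were MX1, FBN1, ADAM9, CTSZ, TGFBR2, CALR, PSAT1, SLFN5, IRF7 and OAS3. For B9 against the mean of the controls it added 9: RIPK1, CTSZ, BMI1, ALDH7A1, LTBP2, ADM, CALR, PSAT1 and DNAJB9. The best partner of 11 of 12 libraries had the same number, and 15 of 18 same-number pairs had r over 0.1 (-0.039 to 0.463, median 0.174, against -0.0878 for other pairs). Without both number 2 control libraries, 6 against 6 gave 1416, the shared genes 152, D7 against A6 0 and the split by genotype 2699. List calls, 4 of 18, were 2 with A6 or D7 left out, 1 with B9 left out, and 0 with an estimated correlation or fry. The cause of these shifts was not tested, except that a larger fold threshold leaves fewer calls by construction.

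Leaving out 1 library gave 6.14 to 6.83 for TLR3, 326 to 1020 for 6 against 6, 53 to 113 for the shared genes, 0 to 4 for D7 against A6 and 867 to 2097 for C12 against B9. The splits gave 889 to 1987, 281 to 803 and 195 to 444, the correlation 0.224 to 0.310, and the lists 2 to 4. Depth limits genes near 1 CPM, where 3 counts are 0.540 to 0.748 CPM.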

Other observations

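Genes in the following 3 paragraphs were chosen after their values were seen. In B9 the interferon-induced genes OASL (2.07), IFIT2 (1.55) and IRF7 (1.34) and the galectin-binding LGALS3BP (1.75) were higher than in the controls, as log2 fold changes called by edgeR. In C12 they stood at -0.23, -0.06, 0.56 and -0.60 and were not called. For OASL (-2.30), IFIT2 (-1.61) and LGALS3BP (-2.35) the difference C12 minus B9 was itself called, and for IRF7 (-0.79) it was not. In C12 the chemokine receptor CXCR4 (-2.07) and the calcium-binding S100A4 (-1.78) were lower than in the controls, and the aldehyde dehydrogenase ALDH1A3 (0.78) was higher.

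DNAJC15, a mitochondrial cochaperone gene on chromosome 13, had 246 counts over the 6 control libraries and 0 over the 6 TLR3 libraries, at least 85.2-fold lower. IGFN1 on chromosome 1 had 140 and 0, at least 48.5-fold lower, and ZNF347 on chromosome 19 had 85 and 0, at least 29.5-fold lower. The other 7 genes that fell at least 8-fold in both clones were BCHE, NAP1L2, RTL8B, LINC00839, ZNF677, ZNF667 and its antisense gene ZNF667-AS1. By the same rule, which asks for 8-fold against each control clone, 0 genes rose in B9, 7 in C12 and 0 in both. TLR3 missed it in B9, with a log2 fold change of 2.81 over A6.

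Averaged over the clones, the stress response genes GDF15, CHAC1 and DDIT3 were higher in number 2 libraries than in numbers 1 and 3. The log2 fold changes were 1.33, 0.98 and 0.86. In C12, library 2 was below library 1 for each, at 15.2 against 20.2 CPM, 132 against 135 and 82.5 against 103. The number 3 libraries were higher in the cold-inducible RBM3 (0.77) and lower in CXCL8 (-2.38) and TNFAIP3 (-1.68). MTND3P25, a nuclear copy of a mitochondrial gene, was at 111 to 150 CPM in A6 library 3, D7 libraries 2 and 3 and B9 library 2, and at most 1.18 CPM in the other 8.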
